A study of Mus musculus with 3 samples.

How the data were processed

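Nuclear RNA was measured in single nuclei from the cortex of 6-month-old 5xFAD mice in 3 libraries, 1 per group, and each library pooled 1 male and 1 female mouse. Per the labels' protocols, all mice received 6 doses of tamoxifen at 100 mg/kg at 4 to 6 weeks of age, with at least 48 h between doses. The TRAP and iPKR mice also received VEGF at 1.0 µg/kg and, after 30.0 minutes, ASV at 5.0 mg/kg, over 4.0 weeks from 5.0 months of age. Nuclei were sorted for high GFP signal and the lowest DyeCycle Ruby signal, and 3' gene expression libraries were made with a target of 8000 nuclei. Per the file headers, the deposited files hold raw UMI counts per gene and nucleus made with Cell Ranger 7.1.0, and per the labels the reads were aligned to mm10. The files list 32285 genes and no scaling was applied to them. Whether reads in introns were counted is not stated, and neither is the exact gene annotation. The filter that chose the barcodes is not stated either, and the lowest UMI totals of a barcode were 501 in TRAP, 501 in iPKR and 500 in Eif2A. Chromosome positions of genes came from a GENCODE vM21 annotation.

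Nuclei with at least 300 genes were kept, which removed 1 nucleus. Doublets were called in each library with Scrublet as held in scanpy 1.11.5, at an expected rate of 6%, and the called ones were removed. It called 0 nuclei in TRAP, 153 in iPKR and 1 in Eif2A, so it has not worked in TRAP and Eif2A, and doublets remain in those libraries. No threshold was set on the mitochondrial share, whose median was 0.311%, 0.0279% and 0.398%. Sex was called per nucleus. A nucleus was male-called with at least 1 UMI of Ddx3y, Uty, Kdm5d or Eif2s3y and at most 1 of Xist, and female-called with at least 2 of Xist and none of those 4 genes. This called 1904 male and 5690 female nuclei in TRAP, 2052 and 2319 in iPKR, and 2174 and 5259 in Eif2A, and 4363, 2183 and 2005 stayed uncalled. Calls depend on depth, so uncalled nuclei were left out only where the sexes are given apart.

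The 3 libraries were clustered together, with 11957, 6401 and 9437 nuclei. The 2000 most variable genes were ranked within each library by variance over mean against genes of like abundance, and the median rank was used, without Xist, Tsix and the Y-linked genes. UMIs were scaled to 10000 per nucleus and log-transformed, and each gene was centred and scaled within each library. From 30 principal components, 20 nearest neighbours per nucleus gave a graph weighted by shared neighbours. It was clustered by the Leiden method at resolution 1.0 with leidenalg 0.10.2, python-igraph 0.11.9 and scikit-learn 1.9.0. Clusters were named from 13 fixed cell type lists, by the list with the highest mean log2 fold against the other nuclei. A class name needed a mean log2 fold of 1 or more for its list and 3 markers at that fold, with 10 CPM added to both sides. Its markers also had to be at least as many among the 10 top genes as those of another class. The nuclei of the microglia class were sub-clustered in the same way and named from 6 fixed lists of microglial states, with 3 markers at a log2 fold of 0.5 or more. A sub-cluster of neuronal genes was taken out of the class, with 3 nuclei of TRAP, 43 of iPKR and 0 of Eif2A. The rules for naming were set after the data were seen.

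Values per library are UMIs summed over the microglia class and scaled to CPM. The sums were 12927058 UMIs over 9251 nuclei in TRAP, 1678173 UMIs over 1436 nuclei in iPKR and 16048005 UMIs over 8632 nuclei in Eif2A. Median UMIs per summed nucleus were 1279, 1116 and 1733. A sum of 3 UMIs, taken as the bound for a count of 0, equals 0.232, 1.79 and 0.187 CPM, so the iPKR library sets the precision of both pairs it enters. Pairs of libraries were compared by the ratio of CPM, with exact Poisson intervals for sums and the exact conditional binomial interval for ratios, all at 95%. Genes at 10 CPM or more in either library entered. No p-value between groups was computed, because nuclei of 1 library are not replicates, and genes were counted by size of fold alone. The 38 gene lists were fixed beforehand, 19 of them for pathways, and 3 lists of ATF4 targets and regulators were joined. A list is given by the median log2 fold of its measured members and its 95% range over 1000 Poisson redraws of the sums. Its percentile is among 10000 random lists, in which each member is replaced by 1 of the 100 genes nearest in mean expression. Members were counted as higher or lower at 1.25-fold. The list of sex genes served the sex calls alone.

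Named genes followed a rule fixed beforehand. Among genes at 50 CPM or more in either library of a pair, Xist, Tsix, Y-linked and mitochondrial genes were left out, as were genes of cell type lists other than microglia. Genes over 3 times higher outside the microglia class were left out too, and names that end in Rik or join Gm, AC, AL or BC to digits. The 10 highest and 10 lowest folds were then taken, at least 1.5-fold in the same direction in both sexes. This condition on the sexes applies where each library holds 200 microglia-class nuclei of each sex, so it was dropped for both pairs with iPKR, which holds 186 male-called ones. Up to 4 members of each list with the largest folds were added, and Eif2s1, Eif2ak2, Eif2ak3, Atf4, Ddit3, Atf3, Eef1a1, Rpl10a, Cx3cr1, P2ry12, Apoe and Trem2 were always named.

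There were 13 alternatives planned before the files were seen. They were TMM factors from edgeR 4.0.16 and size factors from DESeq2 1.42.0 (both used for scaling alone, in R 4.3.3), no filter other than 10 UMIs over both libraries, and 50 CPM or more. Others thinned each nucleus to 1000 UMIs, asked for at least 1000 genes per nucleus, kept the doublets, or took only male-called nuclei, female-called nuclei or the largest sub-cluster with the homeostatic list highest, which stayed unnamed under the naming rules. The remaining ones scaled genes over all libraries together, used Leiden resolution 0.5, or sub-clustered thinned nuclei. A further 6 alternatives were chosen after seeing the data. These removed the highest 6% of each library by doublet score, left out genes over 3 times higher outside the microglia class, used only nuclei of the disease-associated sub-clusters with the state genes kept, thinned the sum of the deeper library, sub-clustered without the genes of the state lists, or drew random lists from genes of the same part of 3 by gene span as well.

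The steps from sums to folds, lists and scaling factors were tested on simulated data with the depths of the real sums. For genes simulated 2-fold higher the median estimated log2 fold was 0.96 for iPKR over TRAP, 1.00 for Eif2A over TRAP and 1.01 for iPKR over Eif2A. The intervals of genes simulated without a difference held the true value for 95.2%, 95.1% and 95.3% of genes. Of 200 simulated lists without a difference, 3, 11 and 6 fell outside the central 95% of random lists. Simulation covered counting noise alone, and no variation between mice or preparations. Other computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and anndata 0.12.19, and figures Matplotlib 3.10.9. Reads that cross the transgenes were not analysed here.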

Results

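RNA was sequenced from single nuclei sorted from the cortex of 6-month-old 5xFAD mice, a transgenic line that forms amyloid plaques. Microglia of these mice carried the ribosomal protein L10a fused to eGFP (the TRAP tag), switched on by tamoxifen through the microglial Cx3cr1 promoter, and nuclei were sorted on that signal. The series asks how the integrated stress response (ISR), the signalling through phosphorylated eIF2 alpha that favours translation of the transcription factor ATF4, affects groups of microglia. There were 3 groups with 1 library each, and each library pooled 1 male and 1 female mouse. The TRAP library, the control, carried the tag alone. The iPKR library carried the tag with an inducible form of the eIF2 alpha kinase PKR, and both of these groups received VEGF and ASV. The Eif2A library carried the A/A genotype of Eif2s1, the gene of eIF2 alpha, with an Eif2s1 transgene, and received tamoxifen only, so that genotype and treatment differ together from the TRAP library. The files held 11958 nuclei and 26788174 unique molecular identifiers (UMIs) for TRAP, 6554 nuclei and 30502700 UMIs for iPKR, and 9438 nuclei and 21782925 UMIs for Eif2A. The median UMIs per nucleus were 1399, 3949.5 and 1778. With 1 library per group no difference has a replicate library and no test between groups was made. All intervals below are 95% intervals that cover counting error only.

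The libraries differed in the kinds of nuclei they held. Microglia-like nuclei, named from genes such as Csf1r and P2ry12, made up 77.4% (76.6 to 78.1) of the TRAP nuclei, 22.4% (21.4 to 23.5) of the iPKR nuclei and 91.5% (90.9 to 92.0) of the Eif2A nuclei, or 9251, 1436 and 8632 nuclei. Neuron-like nuclei made up 16.1% (15.4 to 16.8), 65.5% (64.4 to 66.7) and 5.01% (4.58 to 5.47). Oligodendrocyte-like nuclei were at 2.5%, 4.28% and 0.901%, astrocyte-like nuclei at 1.16%, 2.39% and 0.530%, and oligodendrocyte precursor-like nuclei at 0.995%, 1.91% and 0.265%. Vascular-like nuclei made up 0.468%, 1.58% and 0.307%, and 0.125%, 1.83% and 0.0742% stayed unnamed. Border macrophage-like nuclei, which express Mrc1 and F13a1, made up 1.63% (1.38 to 1.90) of the TRAP microglia-like and border macrophage-like nuclei together, 0.208% (0.0430 to 0.608; 3 nuclei) of those of iPKR and 1.55% (1.30 to 1.83) of those of Eif2A. With genes scaled over all libraries together, border macrophage-like nuclei numbered 11 in iPKR, 0.172% of all its nuclei in place of 0.0469%. All of these shares follow a sort for nuclear GFP signal. With at least 1000 genes asked of each nucleus, the microglia-like shares were 61.1%, 6.58% and 90.1%.

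**Figure D1:**
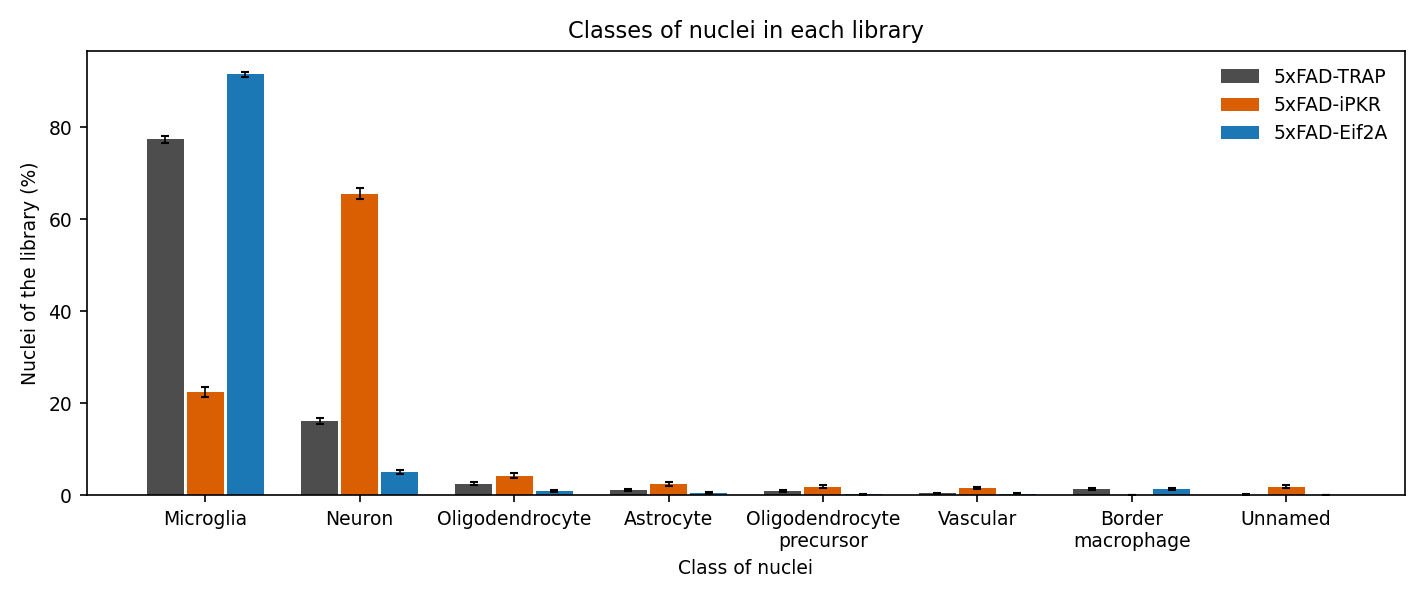
Share of the nuclei of each library (y axis, percent) in each class of nuclei (x axis), with exact binomial intervals as error bars and 1 library per group. Microglia-like nuclei were at 77.4% in the TRAP library, 22.4% in the iPKR library and 91.5% in the Eif2A library.

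Nuclei that resemble disease-associated microglia, the plaque-linked state marked by Apoe, Cst7, Lpl and Trem2, were less frequent in the iPKR library. Sub-clustered without the genes that name the states, a setting chosen after the data were seen, they made up 45.4% (44.4 to 46.4; 4200 nuclei) of the TRAP microglia-like nuclei, 29.5% (27.1 to 31.9; 423 nuclei) of those of iPKR and 49.7% (48.6 to 50.7; 4288 nuclei) of those of Eif2A. Homeostatic-like nuclei, the resting state marked by Tmem119 and P2ry12, were at 51.3%, 68.2% and 47.5% in that clustering. With the state genes kept, named homeostatic-like nuclei made up 30.1%, 10.1% and 26.0%, lowest in iPKR, and 21.4%, 57.7% and 21.6% lay in unnamed sub-clusters with the homeostatic list highest. Cycling-like nuclei, with Top2a and Mki67, numbered 159 (1.72%), 6 (0.418%) and 101 (1.17%). Interferon-responsive nuclei, with Ifit3 and Oasl2, were at 1.55%, 1.88% and 1.66%. In male-called nuclei the disease-associated-like shares were 32.6%, 25.8% and 27.1%, and in female-called nuclei 50.6%, 25.7% and 61.7%. With the state genes kept in the clustering the disease-associated-like shares were 43.4%, 28.6% and 47.6%, and on nuclei thinned to 1000 UMIs they were 29.9%, 20.6% and 32.0%. In the first clustering of all nuclei, the microglia-like nuclei of the libraries fell largely in separate clusters. These were mostly clusters 0, 3 and 4 for TRAP, cluster 5 for iPKR and clusters 1, 2 and 4 for Eif2A. Sub-clusters were more mixed: the largest disease-associated-like one, with the state genes kept, held 1572 TRAP, 126 iPKR and 1613 Eif2A nuclei. Unless stated otherwise, values below sum all microglia-like nuclei of a library, so they largely compare those first clusters.

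**Figure D2:**
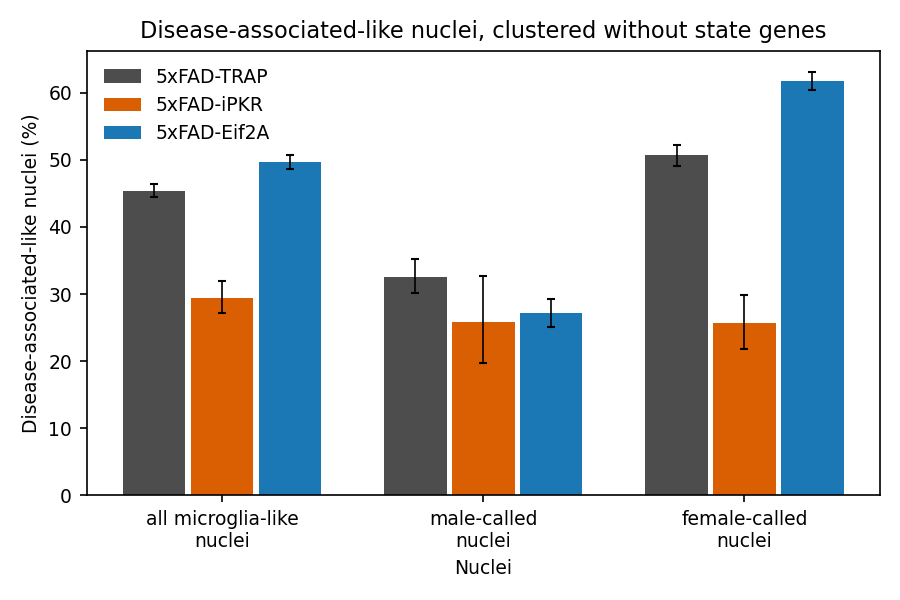
Share of microglia-like nuclei (y axis, percent) that resembled disease-associated microglia, for all nuclei and for male-called and female-called nuclei (x axis), with exact binomial intervals as error bars and 1 library per group. Over all nuclei the shares were 45.4% for TRAP, 29.5% for iPKR and 49.7% for Eif2A.

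The altered gene itself checks no label here. Eif2s1 (ENSMUSG00000021116, mm10 chromosome 12, 78861819 to 78887010) stood at 46.0 CPM (UMIs of the gene per 1000000 UMIs of the summed nuclei) in TRAP, 46.5 in iPKR and 53 in Eif2A microglia-like nuclei. Tags from the 3' end of the RNA do not show the Eif2s1 allele, and the 3' ends of the transgenes are not known from the labels. Eif2ak2, the gene of endogenous PKR, stood at 110, 115 and 100.0 CPM, and Eif2ak3, the gene of the endoplasmic reticulum (ER) kinase PERK, at 74.3, 84.6 and 61.6 CPM. Eef1a1, the locus of the tag, stood at 106, 115 and 167 CPM, and Rpl10a, the endogenous gene of the tagged protein, at 175, 114 and 297 CPM. Both are uncertain because pseudogenes share their sequence.

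The iPKR against TRAP comparison addresses what goes with the inducible kinase in microglia. Disease-associated genes were lower in the iPKR microglia-like nuclei. Homeostatic genes were higher, mainly in female-called nuclei. Apoe (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188), the apolipoprotein gene raised in plaque-associated microglia, stood at 1186 CPM (1134 to 1239) in iPKR and 3156 CPM (3125 to 3187) in TRAP, 2.66-fold lower (2.54 to 2.79). Cst7 (ENSMUSG00000068129, chromosome 2, 150570415 to 150578944), which encodes the protease inhibitor cystatin F, was 3.62-fold lower (3.11 to 4.22). Trem2 (ENSMUSG00000023992, chromosome 17, 48346401 to 48354147), the lipid receptor needed for the disease-associated state, was 1.64-fold lower (1.56 to 1.73). Fcrls (ENSMUSG00000015852, chromosome 3, 87250758 to 87263738), a homeostatic microglial gene, was higher, with a log2 fold of 1.07 (0.99 to 1.15).

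Of 28 disease-associated genes measured at 10 CPM or more in either library, 25 were at least 1.25-fold lower in iPKR and 2 at least that much higher. Their median log2 fold was -0.92 (-0.95 to -0.76), at percentile 0 of 10000 random lists matched on mean expression, with -1.07 in male-called and -0.82 in female-called nuclei. Gpnmb, a glycoprotein of lipid-laden macrophages, was at a log2 fold of -2.00, Cd52 at -1.80 and the growth factor gene Igf1 at -1.65. Of 25 homeostatic genes, 9 were higher and 0 lower, with a median of 0.23 (0.17 to 0.27; percentile 100), at -0.0026 in male-called and 0.34 in female-called nuclei, and they included Crybb1 (1.24), Olfml3 (0.76) and Tmem119 (0.48). P2ry12, the ADP receptor of resting microglia, was at 0.16 and the fractalkine receptor gene Cx3cr1 at 0.21. P2ry12 was at -0.14 in the largest sub-cluster with the homeostatic list highest, which stayed unnamed. The general microglial list of 12 genes had a median of 0.12 (percentile 86.9), with -0.12 in male-called nuclei.

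The 3 lists of ATF4 targets and regulators, which report on ISR output, were slightly higher in iPKR when joined, though not each in both sexes. Their 33 measured genes had a median log2 fold of 0.21 (0.12 to 0.34; percentile 98.5, and 98.9 with gene span matched as well), with 14 higher and 2 lower by 1.25-fold. Cytosolic ribosomal protein genes were higher in this pair as well, 40 of 80 with 4 lower and a median of 0.32 (0.26 to 0.36). The joined ATF4 median was 0.25 in male-called and 0.23 in female-called nuclei, 0.42 in disease-associated-like nuclei alone and 0.11 with DESeq2 scaling factors. Aminoacyl-tRNA synthetase genes, which load amino acids onto tRNAs, gave 7 of 13 higher and 0 lower, a median of 0.32 (0.14 to 0.44; percentile 99.9), led by Yars (0.74), Tars (0.54), Xpot (0.45) and Gars (0.42). The synthetase median was 0.47 in male-called and 0.23 in female-called nuclei. Amino acid synthesis and transport genes gave 4 of 11 higher and 2 lower, a median of 0.18 (-0.13 to 0.33; percentile 75.4), with -0.11 in male-called and 0.27 in female-called nuclei. Among them Phgdh (ENSMUSG00000053398, chromosome 3, 98313170 to 98339990), the first enzyme of serine synthesis, was at 0.95 (0.43 to 1.43) and the folate enzyme gene Mthfd2 at 0.70. The 9 measured ISR transcription factor and feedback genes had a median of 0.21 (percentile 76.8), at -0.015 in male-called and 0.17 in female-called nuclei, with Nupr1 at 0.60, Herpud1 at 0.35, Atf4 at 0.21 (-0.26 to 0.64), Atf3 at 0.19 and Ddit3 at -0.22 (-1.02 to 0.48). The 13 genes of eIF2, eIF2B and their kinases had a median of 0.16 (-0.02 to 0.24) at percentile 88.9. It was 0.18 in male-called and -0.06 in female-called nuclei. Ppp1r15b, which encodes a regulatory subunit of the phosphatase that acts on eIF2 alpha, was at 0.64. In neuron-like nuclei the 25 ATF4 genes measured in both classes had a median of 0.05 (-0.03 to 0.12), against 0.28 in microglia-like nuclei.

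ER chaperone and unfolded protein response genes did not move together. Their 20 measured members had a median of 0.00 (percentile 49.4), with 1 higher and 2 lower. Hspa5, the ER chaperone BiP, was at a log2 fold of -0.62 in male-called and 0.88 in female-called nuclei, and the disulfide isomerase gene Pdia3 at -0.53 and 0.69. Interferon response genes, at a median of -0.21 (-0.30 to -0.06; percentile 0.14), also parted by sex, with 0.53 in male-called and -0.98 in female-called nuclei. MHC class II genes, which present antigen to helper T cells, were higher in 5 of 7 and lower in 1, with a median of 0.92 (0.47 to 1.18; percentile 100). H2-Eb1 was at 2.19 (1.66 to 2.70) from 52 iPKR UMIs, Cd74, the invariant chain, at 1.35 and H2-Ab1 at 0.92. Their median was 2.07 in male-called and 0.14 in female-called nuclei, and -0.29 where only genes at 50 CPM or more entered.

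Cycling genes were lower in 13 of 14, with a median of -1.26 (-1.70 to -0.95; percentile 0), led by Cenpe (-2.80), Knl1 (-2.62) and Top2a (-2.11). These iPKR values rest on 3, 5 and 13 UMIs. Immediate early and inflammatory genes had a median of -0.23 (percentile 0.05), with 4 of 18 higher and 5 lower, including Jund at 1.08, Tnf at -1.12 and the chemokine gene Ccl4 at -0.83. MHC class I genes were lower in 7 of 16 and higher in 1, with a median of -0.29 (-0.50 to -0.17; percentile 0.01), and B2m, the light chain of class I molecules, was at -0.87. Complement genes had a median of -0.16 (percentile 3.56, and 9.51 with random lists matched on gene span as well), with -0.41 in male-called and -0.016 in female-called nuclei, C1qa at -0.29 and the receptor gene C5ar1 at -0.55. Lysosome and phagocytosis genes were lower in 9 of 23 and higher in 0, with a median of -0.22 (-0.29 to -0.15) at percentile 0. They included Cd300lf (-2.50) and the protease genes Ctsa (-0.59) and Ctsh (-0.53). The 19 of them measured in both classes had a median of -0.79 in neuron-like and -0.22 in microglia-like nuclei.

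Cholesterol synthesis genes were lower in 6 of 11 and higher in 0, with a median of -0.44 (-0.75 to -0.22; percentile 0.06), among them Msmo1 (-1.07), Sc5d (-1.02) and the regulator Srebf2 (-0.64). Their median was -0.11 in male-called and -0.81 in female-called nuclei, and 0.14 (-0.57 to 0.63) where the measured genes were chosen again in male-called nuclei alone. Fatty acid and glycerolipid genes had a median of 0.10 (percentile 78.2), with Acaca, which commits acetyl-CoA to fatty acid synthesis, at -1.05. Lipid efflux and droplet genes had a median of -0.08 (percentile 10.9), with the lysosomal sterol carrier Npc2 at -0.67 and the sterol exporter Abcg1 at 0.41. Glycolysis and hypoxia genes had a median of -0.11 (percentile 4.73), with Hif1a at -0.95 and Ldha at -0.76, and oxidative phosphorylation genes 0.04 (percentile 38.9). Oxidative stress and ferroptosis genes had a median of 0.23 (percentile 98.1), with 6 of 16 higher, including the ferritin gene Ftl1 (0.64) and Gclm (0.64). Autophagy genes stood at 0.02 (percentile 42.8), with the autophagy receptor gene Optn at -0.95. Cell death and p53 genes stood at -0.14 (percentile 4.69), with the cell cycle inhibitor gene Cdkn1a at -1.11. TGF-beta genes stood at 0.01 (percentile 56.5), with the ligand gene Tgfb1 at 0.35.

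The genes of highest fold by the size rule also included Col6a3 (1.43), Myo18b (1.28), Upk1b (1.19), Csmd3 (1.14), Myo1d (1.12), Tspan18 (1.08) and Mrc2 (1.05). The lowest also included Lama3 (-4.79, 7 iPKR UMIs), Rab37 (-2.33), the Golgi kinase gene Fam20c (-2.17), Lilrb4a (-1.62), the zinc transporter gene Tmem163 (-1.60) and the phagocytic receptor gene Axl (-1.46). Cd300lf lies within Rab37 on chromosome 11, so the value of either is uncertain. Of 9990 genes, 252 were at least 2-fold higher and 156 at least 2-fold lower in iPKR, while counting noise alone gave 9 and 15 in simulated libraries.

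Neuronal genes were higher beside all of these groups. All 16 synapse and axon genes, such as Csmd1, Nlgn1 and Ptprd, were higher in iPKR microglia-like nuclei, with a median of 0.96 (0.81 to 1.07; percentile 100). Their sum was 1375 CPM in iPKR and 715 CPM in TRAP microglia-like nuclei, against 72054 and 67059 CPM in neuron-like nuclei. The pan-neuronal list had a median of 0.88, with 10 of 10 genes higher. Other cell type lists had few measured genes: astrocyte 3 (median 0.37), oligodendrocyte 4 (-0.22), oligodendrocyte precursor 3 (0.70), excitatory neuron 4 (0.28), inhibitory neuron 2 (0.19), T or NK cell 2 (2.40), B cell 2 (0.96), monocyte or neutrophil 2 (0.62), endothelial 2 (-0.30), border macrophage 1 (-0.34) and mural or fibroblast 0. Without genes over 3 times higher outside the microglia-like nuclei, a setting chosen after the data were seen, 100 genes were 2-fold higher and 151 lower of 9365. The median of all genes was 0.03, and -0.06 with TMM and -0.08 with DESeq2 scaling factors, which gave 181 higher and 208 lower genes and 175 and 220. The higher share was 61.8% with CPM, 46.5% with TMM and 44.3% with DESeq2 factors.

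**Figure D3:**
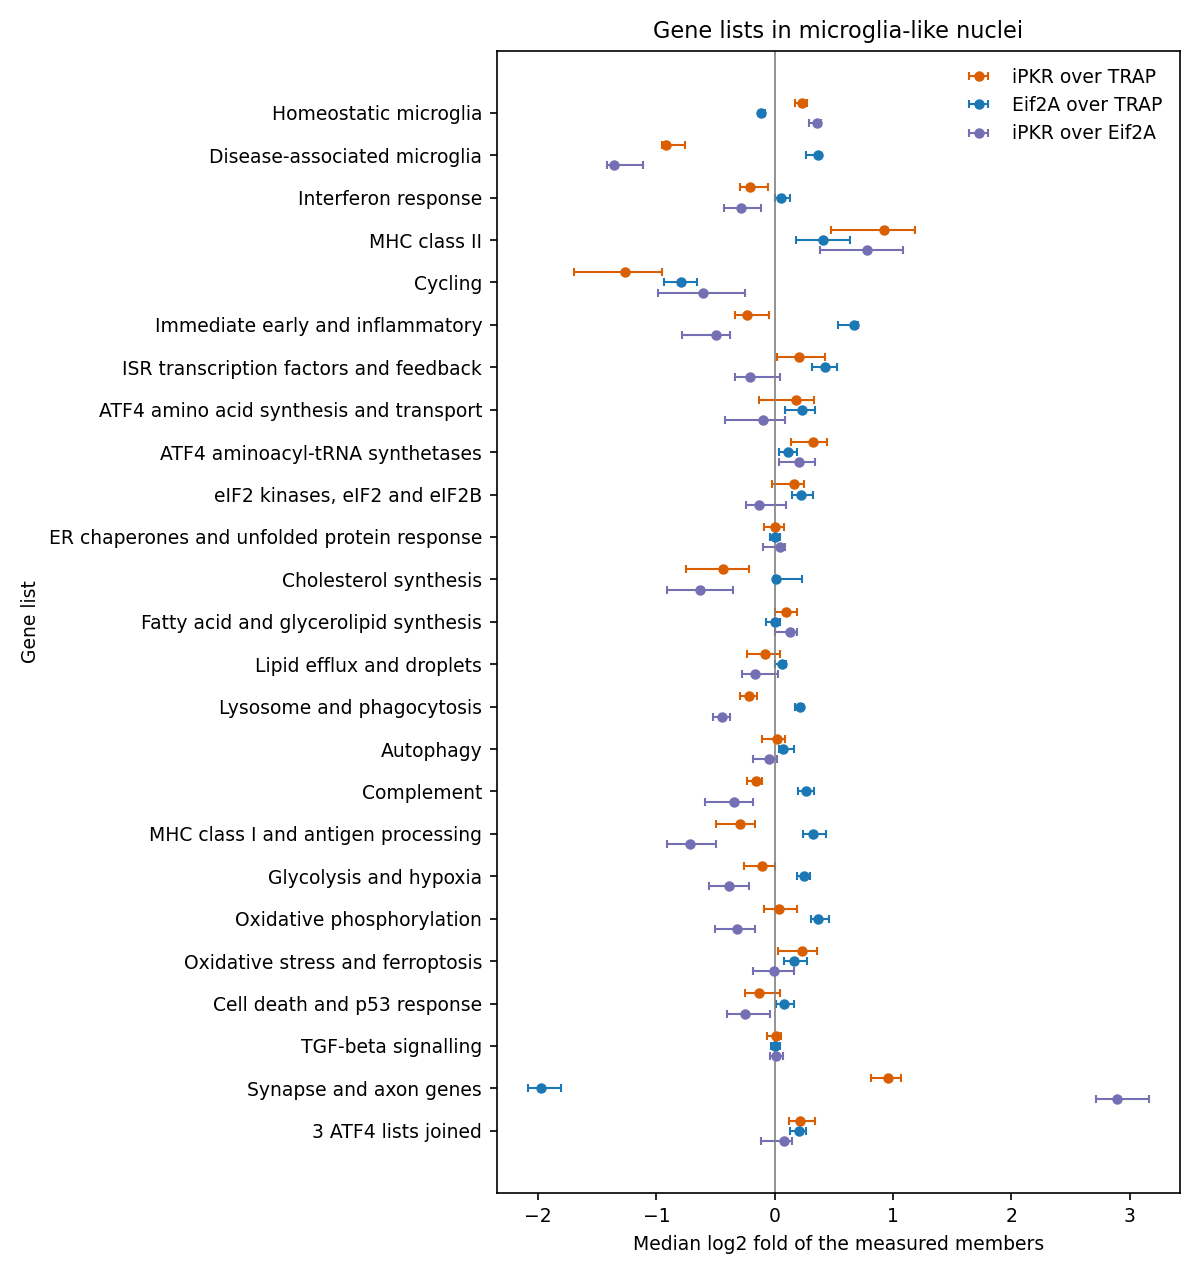
Median log2 fold (x axis) of the measured members of each gene list (y axis) in microglia-like nuclei for the 3 pairs of libraries, with error bars for counting error. The disease-associated list lay at -0.92 for iPKR over TRAP, 0.36 for Eif2A over TRAP and -1.36 for iPKR over Eif2A.

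The Eif2A against TRAP comparison addresses what goes with the altered eIF2 alpha, in mice that also did not receive VEGF and ASV. Disease-associated and immediate early genes were higher in Eif2A microglia-like nuclei, and cycling genes lower. Apoe stood at 5361 CPM (5325 to 5397) in Eif2A and 3156 CPM in TRAP, 1.70-fold higher (1.68 to 1.72), and Trem2 was 1.60-fold higher (1.57 to 1.63). C1qa (ENSMUSG00000036887, chromosome 4, 136895917 to 136898803), which encodes a chain of the complement starter C1q, was at a log2 fold of 0.64 (0.62 to 0.66). Junb (ENSMUSG00000052837, chromosome 8, 84974484 to 84978718), an immediate early transcription factor gene, was at 1.10 (0.92 to 1.28). Atf4 (ENSMUSG00000042406, chromosome 15, 80255184 to 80257541) was higher, not lower, at 38.1 CPM (35.1 to 41.2) against 25.3 CPM (22.6 to 28.2).

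Of 29 disease-associated genes, 15 were at least 1.25-fold higher and 1 lower, with a median log2 fold of 0.36 (0.27 to 0.37; percentile 100), 0.05 in male-called and 0.44 in female-called nuclei. In neuron-like nuclei the 19 of these genes measured in both classes had a median of 0.30 (0.23 to 0.39), against 0.37 in microglia-like nuclei. For iPKR over TRAP 18 of them were at -3.35 in neuron-like nuclei, against -0.92 in microglia-like nuclei, but so were other microglial genes, with 22 homeostatic genes at -2.66 against 0.21 and 5 complement genes at -3.80 against -0.14. Free microglial RNA in neuron-like nuclei was not ruled out in either pair. Cd68, a lysosomal membrane gene of phagocytes, was at 0.76 and the protease gene Ctsd at 0.52. Homeostatic genes had a median of -0.11 (percentile 15.2), with 2 of 25 higher and 2 lower, the ectoenzyme gene Entpd1 at -0.43, Selplg at 0.39, P2ry12 at -0.14 and Cx3cr1 at -0.12. The general microglial list had a median of -0.19 (percentile 4.87), with Runx1 at -0.38 and Csf1r at -0.26. Lysosome and phagocytosis genes were higher in 7 of 23 and lower in 0, led by Cd300lf (0.56), Ctsl (0.50) and Tfe3 (0.48). Their median was 0.21 (0.17 to 0.24; percentile 99.955, but 92.1 with gene span matched as well). Complement genes were higher in 5 of 10 and lower in 1, with a median of 0.27 (percentile 99.5, but 82.0 with gene span matched as well). They included C1qb (0.58), C1qc (0.53) and C5ar2 (0.59). MHC class I genes were higher in 8 of 16 and lower in 0, with a median of 0.32 (percentile 99.6, but 67.0 with gene span matched as well). Their median was 0.04 in male-called and 0.41 in female-called nuclei, and they included H2-T23 (0.90), H2-D1 (0.62) and the peptide transporter gene Tap2 (0.64). H2-Q7 (0.66) shares sequence with its neighbours and is uncertain.

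Immediate early and inflammatory genes were higher in 13 of 18 and lower in 0, with a median of 0.67 (0.53 to 0.70; percentile 100), among them the endotoxin co-receptor gene Cd14 (1.09), Ier5 (0.85) and Ier3 (0.83). In neuron-like nuclei the 5 of these genes measured in both classes had a median of 0.70, against 0.81 in microglia-like nuclei. Cycling genes were lower in 12 of 15 and higher in 0, with a median of -0.80 (-0.94 to -0.66; percentile 0), led by the proliferation marker gene Mki67 (-2.22), Cenpe (-1.25) and Kif11 (-1.24). Interferon genes stood at 0.05 (percentile 33), with -0.21 in male-called and 0.18 in female-called nuclei, and Oasl2 at 0.53. The 5 measured MHC class II genes had a median of 0.40 (percentile 95.8), with 0.33 in male-called and 0.69 in female-called nuclei, and -0.68 where the measured genes were chosen again in male-called nuclei alone. The peptide-loading gene H2-DMa was at 0.65, and Cd74 at -0.73 in male-called and 0.70 in female-called nuclei.

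The joined ATF4 lists had a median of 0.21 (0.13 to 0.26; percentile 95) over 32 genes, 11 higher and 3 lower, within the range of random lists, -0.07 to 0.23. The median was 0.33 where only genes at 50 CPM or more entered and 0.13 without a filter on CPM. ISR transcription factor and feedback genes were higher in 5 of 8 and lower in 1. Their median was 0.43 (0.32 to 0.52; percentile 99.1, but 94.1 with gene span matched as well). They included Atf4 (0.59), Cebpb (0.59), Herpud1 (0.55) and Nupr1 (0.53), while Ddit3 was at 0.28 and Atf3 at 0.09. Amino acid genes had a median of 0.23 (percentile 85.1), with Mthfd2 at 0.68 and the transporter genes Slc38a2 at 0.58 and Slc3a2 at 0.48. Aminoacyl-tRNA synthetase genes had a median of 0.12 (percentile 64.2), with Tars at -0.64 and Yars at 0.42. Genes of eIF2, eIF2B and their kinases had a median of 0.22 (percentile 89.5), with Eif2b4 at 0.68 and the amino acid sensor kinase gene Eif2ak4 at -0.40. In neuron-like nuclei the 25 ATF4 genes measured in both classes had a median of 0.25 (0.11 to 0.33), against 0.20 in microglia-like nuclei. ER chaperone genes stood at 0.00 (percentile 31.9), with Hsp90b1 at -0.42 and Sdf2l1 at 0.38.

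Oxidative phosphorylation genes were higher in 14 of 23 and lower in 0, with a median of 0.37 (percentile 99.8), including Cox8a (0.85), Atp5a1 (0.80) and Cox4i1 (0.63), and the median in neuron-like nuclei was also 0.37. Glycolysis and hypoxia genes were higher in 8 of 21 and lower in 0, with a median of 0.25 (percentile 98.8) in microglia-like and 0.25 in neuron-like nuclei, led by Gapdh (0.71) and Slc16a3 (0.64). Short genes were higher in general in this pair: those with spans under 16.3 kb had a median of 0.29, and 61 of 80 cytosolic ribosomal protein genes were higher and 0 lower, with a median of 0.46. With random lists matched on gene span as well, a setting chosen after the data were seen, the percentiles were 92.4 for oxidative phosphorylation, 96.8 for glycolysis, 96.4 for the joined ATF4 lists and 94.1 for ISR transcription factors. They were 99.9 for disease-associated, 92.1 for lysosome, 82.0 for complement, 67.0 for MHC class I, 100 for immediate early, 0.845 for homeostatic, 3.83 for ER chaperone, 83.2 for MHC class II, 66.8 for fatty acid and 63.5 for oxidative stress genes. Oxidative stress genes had a median of 0.16 (percentile 81.0), with Ftl1 at 0.87 and the lipid peroxide reductase gene Gpx4 at 0.66. Lipid efflux and droplet genes stood at 0.06 (percentile 67.4), with the droplet coat gene Plin2 at 0.74 and the exporter gene Abca1 at -0.46. Cholesterol synthesis genes stood at 0.01 (percentile 29.6), with -0.12 in male-called and 0.15 in female-called nuclei. Fatty acid genes stood at 0.00 (percentile 27.8), with Elovl1 at 0.67. Autophagy genes stood at 0.07 (percentile 58.5), with the receptor gene Sqstm1 at 0.74 and Gabarapl2 at 0.67. Cell death and p53 genes stood at 0.08 (percentile 55.4), with the pore-forming gene Bax at 0.96. TGF-beta genes stood at 0.00 (percentile 62.5), with the inhibitor gene Smad7 at 0.53.

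Of 9805 genes, 65 were at least 2-fold higher and 420 at least 2-fold lower in Eif2A, against 0 and 0 from counting noise in simulated libraries. Those of highest fold by the size rule included Atpif1 (1.18), which inhibits the mitochondrial ATP synthase, Fam53b (1.13), Glmp (1.10), the mitochondrial protease gene Clpp (1.07), Rps2 (1.03; uncertain, with pseudogenes), Bmyc (1.02) and Snhg20 (1.00). The lowest were Masp2 (-2.49; ENSMUSG00000028979, chromosome 4, 148602554 to 148615499), AY036118 (-2.01), Lrrn3 (-1.74), Lrrc18 (-1.68), Paqr3 (-1.67), Pard3bos1 (-1.60), Vxn (-1.58), the potassium channel gene Kcnj13 (-1.53), Lysmd4 (-1.48) and Insyn2a (-1.45). AY036118 is uncertain because it shares sequence with ribosomal RNA. Many of these genes were lower in other nuclei of the library as well. Leaving out genes over 3 times higher outside the microglia-like nuclei, 164 of the 2-fold lower genes could be measured in neuron-like nuclei, and 163 of them were lower there, with a median of -1.40 (-1.46 to -1.33) against -1.34 in microglia-like nuclei. Of the 2-fold higher genes, 34 could be measured in neuron-like nuclei, and 34 of them were higher there, with a median of 0.97. In the iPKR over TRAP pair the same check gave medians of -0.05 for 20 higher genes and -0.07 for 58 lower genes in neuron-like nuclei.

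**Figure D4:**
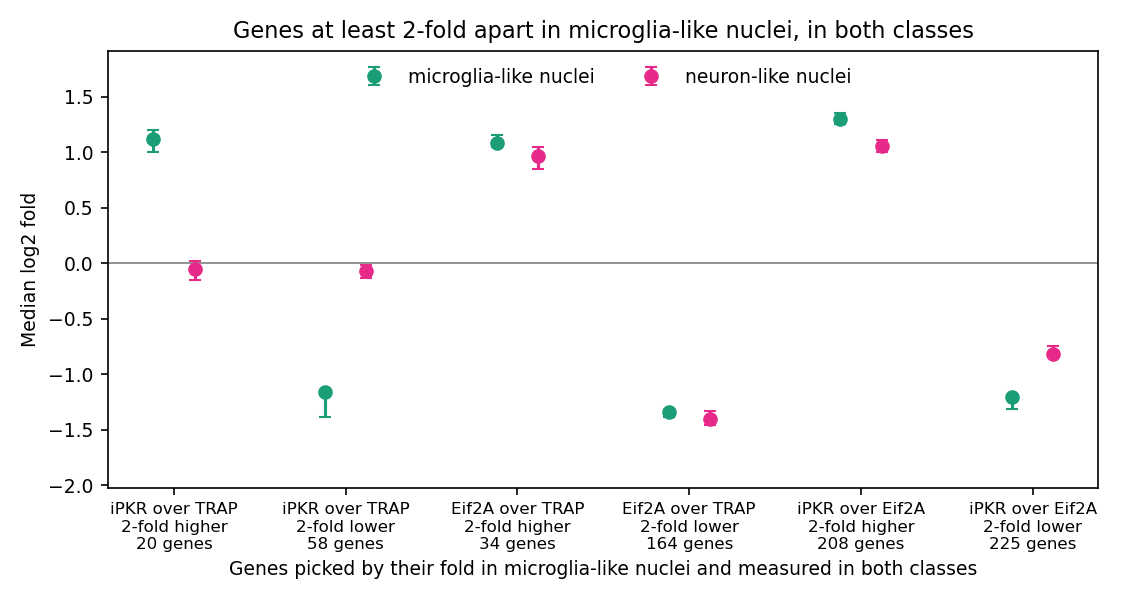
Median log2 fold (y axis) in microglia-like and in neuron-like nuclei of the genes at least 2-fold higher or lower in microglia-like nuclei of each pair of libraries (x axis), with error bars for counting error. The genes 2-fold lower in Eif2A than in TRAP lay at -1.34 in microglia-like and -1.40 in neuron-like nuclei.

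Synapse and axon genes were lower in 16 of 16 in Eif2A microglia-like nuclei, with a median of -1.97 (-2.09 to -1.81; percentile 0) and a sum of 231 CPM, led by Dlg2 (-2.79), Lrrtm4 (-2.78) and Fgf14 (-2.70). Pan-neuronal genes were lower in 8 of 9, with a median of -1.64. The other cell type lists gave astrocyte 3 genes (median -0.73), oligodendrocyte 4 (-0.30), oligodendrocyte precursor 1 (-2.30), excitatory neuron 3 (-0.01), inhibitory neuron 2 (-1.42), B cell 3 (0.20), monocyte or neutrophil 1 (0.25), endothelial 2 (0.06), mural or fibroblast 1 (0.41), border macrophage 1 (-0.74) and T or NK cell 0. Without genes over 3 times higher outside the microglia-like nuclei the counts were 65 higher and 295 lower of 9384.

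The iPKR against Eif2A comparison sets the kinase library beside the altered eIF2 alpha library. Disease-associated and lysosomal genes were lower in iPKR microglia-like nuclei. Homeostatic genes were higher and MHC class I genes lower, mainly in female-called nuclei. Apoe was 4.52-fold lower (4.32 to 4.73), Cst7 4.64-fold lower (4.01 to 5.42) and Trem2 2.62-fold lower (2.49 to 2.77). H2-T23 (ENSMUSG00000067212, chromosome 17, 36029773 to 36032855), a nonclassical class I gene, was at a log2 fold of -2.08 (-2.45 to -1.72). Crybb1, a homeostatic gene, was at 1.57 (1.27 to 1.86).

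Disease-associated genes were lower in 24 of 29 and higher in 1, with a median of -1.36 (-1.42 to -1.11; percentile 0), and Cd52 was at -2.19 and Gpnmb at -2.10. Homeostatic genes were higher in 14 of 25 and lower in 1, with a median of 0.36 (0.29 to 0.39; percentile 99.9), at 0.03 in male-called and 0.42 in female-called nuclei, including Fcrls (0.91), Olfml3 (0.85) and Tmem119 (0.69), with P2ry12 at 0.30 and Cx3cr1 at 0.33. The general microglial list had a median of 0.32 (percentile 94.6), with Csf1r at 0.57. MHC class I genes were lower in 12 of 16 and higher in 0, with a median of -0.72 (percentile 0), at -0.05 in male-called and -0.80 in female-called nuclei, H2-D1 at -1.23 and H2-K1 at -1.10. Complement genes were lower in 6 of 10 and higher in 1, with a median of -0.35 (percentile 1.83) and C1qa at -0.93, but with gene span matched as well the percentile was 14.3, within the range of random lists. Lysosome genes were lower in 16 of 23 and higher in 1, with a median of -0.45 (percentile 0), including Cd300lf (-3.07) and the glucuronidase gene Gusb (-0.93). The 20 lysosome genes measured in both classes had a median of -0.65 in neuron-like and -0.44 in microglia-like nuclei. For 18 disease-associated genes these medians were -3.84 and -1.38, and for 19 homeostatic genes -1.44 and 0.33. Free microglial RNA in neuron-like nuclei was not ruled out in this pair. MHC class II genes were higher in 4 of 7 and lower in 2, with a median of 0.78 (percentile 99.7), H2-Eb1 at 3.91 (3.26 to 4.59) and H2-DMb1 at -1.08. Their median was 2.81 in male-called and -0.13 in female-called nuclei, -0.80 where the measured genes were chosen again in female-called nuclei alone, -0.94 where only genes at 50 CPM or more entered and -1.07 in the largest sub-cluster with the homeostatic list highest, which stayed unnamed. Interferon genes stood at -0.28 (percentile 3.63), with 0.74 in male-called and -1.18 in female-called nuclei, and Oasl2 at 1.18 and -2.04.

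The joined ATF4 lists stood at 0.08 (-0.12 to 0.15; percentile 84.3) over 33 genes, 9 higher and 8 lower, with 0.23 in disease-associated-like nuclei alone and -0.11 with TMM factors. Aminoacyl-tRNA synthetase genes were higher in 4 of 13 and lower in 0, with a median of 0.20 (percentile 92.8), and Tars (ENSMUSG00000022241, chromosome 15, 11382301 to 11399665) was at 1.18 (0.68 to 1.65). Amino acid genes stood at -0.10 (percentile 34.8), with Phgdh at 0.88 and Psat1, another serine synthesis gene, at -0.70. ISR transcription factor genes stood at -0.21 (percentile 19.5), with Jdp2 at 0.70, Cebpb at -0.60, Atf4 at -0.38 (-0.83 to 0.04) and Ddit3 at -0.51. Genes of eIF2, eIF2B and their kinases stood at -0.13 (percentile 25.8), with Eif2b4 at -0.69 and Ppp1r15b at 0.69. ER chaperone genes stood at 0.04 (percentile 78.3), with -0.39 in male-called and 0.27 in female-called nuclei, and Hspa5 at -0.42 and 1.18. Cycling genes were lower in 6 of 9 and higher in 1, with a median of -0.61 (percentile 0.585), Top2a at -1.29 and Cenpf at 0.83. Immediate early and inflammatory genes were lower in 13 of 19 and higher in 1, with a median of -0.49 (percentile 0.11), Cd14 at -1.56, Junb at -1.41 and the cytokine gene Il1b at 1.59. The 5 of them measured in both classes had a median of -0.75 in neuron-like and -0.49 in microglia-like nuclei.

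Cholesterol synthesis genes were lower in 8 of 12 and higher in 0, with a median of -0.63 (percentile 0.1) and Msmo1 at -1.07. Their median was 0.20 in male-called and -0.91 in female-called nuclei, and 0.35 (-0.46 to 0.71) where the measured genes were chosen again in male-called nuclei alone. Glycolysis and hypoxia genes were lower in 12 of 21, with a median of -0.39 (percentile 0.24), the oxygen sensor gene Egln3 at -1.85 and Ldha at -1.34. Oxidative phosphorylation genes were lower in 12 of 23, with a median of -0.32 (percentile 1.95) and Cox8a at -1.01. With gene span matched as well they lay within the range of random lists, -0.43 to 0.08, and in neuron-like nuclei 21 of them had a median of -0.45. Genes with spans under 16.3 kb had a median of -0.23 in this pair. The span-matched percentiles were 0.41 for glycolysis, 0.18 for MHC class I, 0.12 for lysosome 3.23 for immediate early, 41.2 for ISR transcription factor, 90.9 for ER chaperone and 73.3 for fatty acid genes. Fatty acid genes stood at 0.13 (percentile 91.8), with -0.10 in male-called and 0.03 in female-called nuclei and Acaca at -1.14. Lipid efflux genes stood at -0.17 (percentile 12.5), with Plin2 at -1.26 and Abca1 at 0.80. Autophagy genes stood at -0.05 (percentile 47.4), with Sqstm1 at -1.06. Oxidative stress genes stood near 0 (percentile 54.3), with 0.12 in male-called and -0.25 in female-called nuclei and Gpx4 at -0.92. Cell death genes stood at -0.25 (percentile 6.07), with Bax at -1.22. TGF-beta genes stood at 0.01 (percentile 46.3), with Smad3 at 0.53 and Nrros at -0.61.

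The highest genes by the size rule were AY036118 (2.50), Col6a3 (2.20), Myo18b (1.98), Upk1b (1.95), Mboat1 (1.93), Myo1d (1.76), Mrc2 (1.75), Vxn (1.67), Kcnj13 (1.67) and Pard3bos1 (1.59). The lowest were Ankrd55 (-6.85, -12.15 to -4.37, from 1 iPKR UMI), Lama3 (-4.44), the cholesterol hydroxylase gene Ch25h (-3.15), Pianp (-3.11), Cd300lf (-3.07), Fxyd5 (-2.84), Fam20c (-2.46), the protease gene Ctse (-2.35), Cst7 (-2.22) and Cd52 (-2.19). Of 10184 genes, 805 were 2-fold higher and 422 lower, against 6 and 22 from counting noise. Synapse genes were higher in 16 of 16, with a median of 2.90 (percentile 100), and pan-neuronal genes at 2.33. The other cell type lists gave astrocyte 3 genes (median 1.19), oligodendrocyte 4 (0.08), oligodendrocyte precursor 3 (2.95), excitatory neuron 4 (0.44), inhibitory neuron 2 (1.61), T or NK cell 2 (3.44), B cell 3 (0.53), monocyte or neutrophil 2 (0.76), endothelial 2 (-0.36), mural or fibroblast 1 (-3.39) and border macrophage 1 (0.40). Without genes over 3 times higher outside the microglia-like nuclei 462 were higher and 419 lower of 9569. The higher share of 65.6% became 50.8% with TMM and 51.7% with DESeq2 factors, which moved the median of all genes from -0.02 to -0.15 and -0.14 (643 higher and 623 lower, and 650 and 607). Of the genes open to the neuron check, 208 of the higher had a median of 1.06 and 225 of the lower a median of -0.82 in neuron-like nuclei.

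The folds of iPKR over TRAP and of Eif2A over TRAP had a weak negative correlation. Across 3560 genes at 50 CPM or more in all 3 libraries, which are not independent replicates, it was -0.117, with a covariance of -0.00900. Some lists moved the same way in both pairs, such as the joined ATF4 lists (0.21 and 0.21) and cycling genes (-1.26 and -0.80). The disease-associated list moved in opposite ways (-0.92 and 0.36). Unchanged libraries simulated against the same control gave 0.253 and 0.00141, so the shared control pulls the correlation upwards. A single control library cannot be split into independent parts.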

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

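The tests of explanations in this part were set before their results were seen, while the sub-clustering behind the shares of disease-associated-like nuclei was chosen after the data were seen. Several values differed in direction between male-called and female-called nuclei, and the genes and lists among them had counting intervals on one side of 0. Each sex of a library is a single mouse, so sex and animal are the same comparison here, and none of these differences was tested. For iPKR over TRAP the interferon list had a median log2 fold of 0.53 in male-called and -0.98 in female-called nuclei, and the ER chaperone list -0.33 and 0.27. Among single genes of that pair, Eif2ak2 was at 1.13 and -0.83, Hspa5 at -0.62 and 0.88, and Pdia3 at -0.53 and 0.69. For Eif2A over TRAP the interferon list was at -0.21 and 0.18 and Cd74 at -0.73 and 0.70. For iPKR over Eif2A the interferon list was at 0.74 and -1.18, the ER chaperone list at -0.39 and 0.27, Eif2ak2 at 1.5 and -0.78, Oasl2 at 1.18 and -2.04, and Hspa5 at -0.42 and 1.18. The share of disease-associated-like nuclei was -5.45 percentage points apart in male-called nuclei and 11.1 points apart in female-called nuclei (Eif2A minus TRAP), without an interval. With male-called nuclei sub-clustered alone the shares were 28.8% (26.4 to 31.3) in TRAP and 28.1% (26.1 to 30.2) in Eif2A. The male-called iPKR values rest on 186 microglia-like nuclei. No explanation of these sex differences was tested.

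Neuron-like nuclei, which are not part of the microglia sums, made up 65.5% of the iPKR library and 16.1% of the control, in spite of a sort for GFP and the lowest DyeCycle Ruby. Beside them, synapse and axon genes were higher in iPKR than in TRAP microglia-like nuclei, with a median log2 fold of 0.96 and sums of 1375 and 715 CPM against 72054 and 67059 CPM in neuron-like nuclei. Among the nuclei kept, doublets of a neuron and a microglial nucleus are argued against as the source. The 72 nuclei richest in these genes, the top 5%, carried 17.0% of the synapse UMIs, where an even spread gives 13.3%. The 153 called iPKR doublets and 43 iPKR nuclei of a sub-cluster of neuronal genes had been removed before. That removal favours an even spread, so the test does not speak on doublets before it. Expression by iPKR microglia alone is argued against too, since the list was also higher in iPKR oligodendrocyte-like nuclei, at 1.26 (0.85 to 1.49). The sums there were 9466 CPM in iPKR and 6842 CPM in TRAP, a smaller difference than the median gives. Free neuronal RNA in the droplets may be the source, but it stays open: across 1309 genes, which are not independent replicates, the excess in iPKR microglia-like nuclei followed the level in neuron-like nuclei with r 0.659 (Spearman 0.512), between the bounds set for and against. All 16 genes of the list were measured in microglia-like nuclei, and a difference that goes with the kinase was not tested apart from the library.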

How the results depend on the processing

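The main settings and 13 alternatives were chosen before the data were examined, apart from the rules for naming clusters, and 6 more alternatives were chosen after seeing the data. Those 6 are marked as added. No paired analysis was possible because the labels give no replicate numbers and each group has 1 library. The sexes were compared apart as a check of direction, fixed beforehand, and not as replicates, since both mice of a group share its library. Of 5237 values of named genes under the alternatives, 5115 kept their sign, and of 1104 list medians 990 did, while 6 and 10 reversed with both counting intervals clear of 0. The joined ATF4 median kept within its counting range in 37 of 42 values, the counts of 2-fold genes stayed within 1.5 times in 49 of 84, and shares moved in 74 of 159. Some of these values could not change. Leaving out genes over 3 times higher outside the class removed no ATF4 gene, and keeping doublets left the Eif2A and TRAP sums as they were. Over the alternatives the disease-associated median ranged from -1.12 to -0.52 for iPKR over TRAP, from 0.03 to 0.44 for Eif2A over TRAP and from -1.54 to -0.77 for iPKR over Eif2A, and the homeostatic median for iPKR over TRAP from -0.0026, in male-called nuclei, to 0.34. The joined ATF4 median for iPKR over Eif2A ranged from -0.11, with TMM factors, to 0.23. The cycling median ranged from -1.58 to 0.31 for iPKR over TRAP, its highest value in disease-associated-like nuclei alone, which leave cycling nuclei out by construction. With male-called nuclei only, the interferon median was 0.57 for iPKR over TRAP, -0.16 for Eif2A over TRAP and 0.76 for iPKR over Eif2A, and the general microglial list -0.12 for iPKR over TRAP. Hspa5 was then at -0.62 over TRAP and -0.42 over Eif2A, Pdia3 at -0.53 (iPKR over TRAP), Oasl2 at 1.18 (iPKR over Eif2A), and the MHC class II list at -0.68 and Cd74 at -0.73 (Eif2A over TRAP). The 2-fold counts were 930 higher and 798 lower for iPKR over TRAP, 201 higher for Eif2A over TRAP, and 1264 higher and 1060 lower for iPKR over Eif2A, and disease-associated-like shares 28.8%, 21.2% and 28.1% (TRAP, iPKR, Eif2A). With female-called nuclei only, MHC class II was at -0.80 for iPKR over Eif2A, the counts were 545 and 431 (iPKR over TRAP), 98 higher (Eif2A over TRAP) and 831 lower (iPKR over Eif2A), and the shares 48.1%, 31.7% and 56.5%. At 50 CPM or more, MHC class II was at -0.29 for iPKR over TRAP and -0.94 for iPKR over Eif2A, and the ATF4 median at 0.33 for Eif2A over TRAP. The counts there were 34 and 34, 9 and 89, and 184 and 131 for iPKR over TRAP, Eif2A over TRAP and iPKR over Eif2A, with fewer genes entering. Without a filter they were 1186 and 688, 439 and 2099, and 2485 and 956, with the ATF4 median at 0.13 and the B cell list at -0.69 for Eif2A over TRAP. With at least 1000 genes per nucleus, the counts were 969 and 496 for iPKR over TRAP and 1315 and 837 for iPKR over Eif2A. In the order TRAP, iPKR, Eif2A, the shares were then 38.0%, 20.8% and 40.4% disease-associated-like, 61.1%, 6.58% and 90.1% microglia-like, and 31.5%, 86.3% and 6.75% neuron-like. In the largest sub-cluster with the homeostatic list highest, which stayed unnamed, P2ry12 was at -0.14 (iPKR over TRAP) and MHC class II at -1.07 (iPKR over Eif2A), with 247 lower for iPKR over TRAP and 204 higher for Eif2A over TRAP. In disease-associated-like nuclei only (added), the ATF4 median was 0.42 for iPKR over TRAP and 0.23 for iPKR over Eif2A, with 700 and 350 genes for iPKR over TRAP, 112 higher for Eif2A over TRAP and 637 lower for iPKR over Eif2A. With random lists matched on gene span as well (added), list percentiles left their counting range in 73 of 94 values, and for Eif2A over TRAP MHC class I went from 99.6 to 67.0 and complement from 99.5 to 82.0. DESeq2 factors gave an ATF4 median of 0.11 for iPKR over TRAP. Nuclei thinned to 1000 UMIs gave 244 lower for iPKR over TRAP, and the deeper sum thinned (added) 402 higher. Without genes over 3 times higher outside the class (added), 100 were higher for iPKR over TRAP and 462 for iPKR over Eif2A. Disease-associated-like shares were 44.7%, 21.6% and 50.9% with genes scaled over all libraries together and 29.9%, 20.6% and 32.0% on thinned nuclei. Clustered without the state genes (added), they were 45.4% for TRAP and 49.7% for Eif2A. For these values the cause was not tested, except that stricter or absent filters and fewer nuclei change how many genes enter and their counting noise by construction. In each of these settings the iPKR share of disease-associated-like nuclei was the lowest of the 3 libraries. With male-called nuclei only, however, the iPKR interval (15.6 to 27.7) overlapped those of TRAP (26.4 to 31.3) and Eif2A (26.1 to 30.2). The iPKR sum of 1678173 UMIs limits both pairs it enters, and counting noise alone gave 9 and 15 genes for iPKR over TRAP, 0 and 0 for Eif2A over TRAP, and 6 and 22 for iPKR over Eif2A.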

Other observations

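Of the tests in this part, only the one on nuclei thinned to 1000 UMIs was set before its result was seen, and those on neuron-like nuclei, gene length, genes of other nuclei, the mix of nuclei and the homeostatic list were chosen after. Disease-associated-like nuclei are here those of the clustering with the state genes kept. Some folds of the report rest on nuclei of 1 sex or on few nuclei. Lama3 stood at 157 CPM in female-called and 12.3 CPM in male-called TRAP microglia-like nuclei, at 134 CPM and 0.293 CPM (1 UMI) in Eif2A, and at 5.26 CPM (3 UMIs) and 8.24 CPM (2 UMIs) in iPKR. Ankrd55 stood at 45.1 and 13.3 CPM in TRAP and 94.2 and 7.90 CPM in Eif2A, and had 0 UMIs in female-called and male-called iPKR nuclei, where 3 UMIs equal 5.26 and 12.4 CPM. In male-called iPKR nuclei, most Cd74 and H2-Eb1 UMIs came from 44 disease-associated-like nuclei. Cd74 stood there at 1457 CPM (74 UMIs) and H2-Eb1 at 591 CPM (30 UMIs), against 83.3 CPM and 5.21 CPM (1 UMI) in the other 142 male-called iPKR nuclei. In male-called disease-associated-like TRAP nuclei they stood at 101 and 14.9 CPM.

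Apoe was ordered alike inside and outside the disease-associated-like nuclei, at 6192 CPM in TRAP, 3138 in iPKR and 9007 in Eif2A inside, and 925, 474 and 1986 CPM outside. Csf1r, which neurons should lack, stood at 74.5, 3.43 and 36.9 CPM in neuron-like nuclei. In the Eif2A over TRAP pair, with the genes split by span into 3 equal parts, 62 of the 2-fold higher genes had spans under 16.3 kb, 2 had spans up to 43.1 kb and 1 a longer one, with median log2 folds of 0.29, 0.09 and -0.06 over all genes of these parts. AY036118 stood at 809, 983 and 146 CPM in neuron-like, 1225, 1595 and 315 CPM in oligodendrocyte-like and 1317, 1596 and 209 CPM in astrocyte-like nuclei of TRAP, iPKR and Eif2A.

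Many genes were at least 2-fold lower in Eif2A than in TRAP microglia-like nuclei. A difference in unspliced RNA that follows gene length is argued against, since 20.5% (16.1 to 25.6) of 292 such genes had spans over 43.1 kb, the longest of those 3 parts, and 140 genes had spans under 16.3 kb. Less free RNA of other cells is argued against as the whole source, since 70.0% of them, 292 of 417 with Xist, Tsix, Y-linked and mitochondrial genes aside, were left without genes over 3 times higher outside the microglia-like nuclei. What stays open is a difference that acts beyond microglia-like nuclei, checked for these genes as a set in neuron-like nuclei alone. There 164 of them could be measured and had a median of -1.40 (-1.46 to -1.33), where random lists of like expression gave -0.23 to -0.05. Such a difference may lie in the preparation, in the mapping, whose gene annotation is not stated, or in the mice. The genotype and the missing VEGF and ASV are untested parts of that, since they differ together in 1 library. Free microglial RNA could also carry a microglial fold into neuron-like nuclei, and it was not ruled out. In neuron-like nuclei of TRAP and Eif2A the homeostatic list summed to 2167 and 1680 CPM, and the disease-associated list to 1284 and 1548 CPM.

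Disease-associated genes were lower in iPKR than in TRAP microglia-like nuclei, at a median of -0.92. TRAP nuclei mixed at the iPKR shares of disease-associated-like nuclei gave 37.4% of it (-0.34). The list was at -0.52 (-0.67 to -0.45) within those nuclei and at -0.76 (-0.87 to -0.56) within the others. These values cannot decide whether a smaller share is the whole cause, since these same genes helped to part the nuclei. Genes were also scaled within each library before clustering, so a shift across a whole library does not enter the calls. The shares were 43.4% in TRAP and 28.6% in iPKR, and 44.7% and 21.6% with genes scaled over all libraries together. With each nucleus thinned to 1000 UMIs the median was -0.97 (-1.02 to -0.80). This cannot decide on shallower nuclei, since thinning leaves the expected share of a gene in a nucleus unchanged and the class calls were kept. Dilution by neuronal RNA is argued against as the whole source by the homeostatic list, which was higher, at 0.23 (0.17 to 0.27). That list was not higher in male-called nuclei. A smaller share of disease-associated-like nuclei could also raise it, so a part by dilution stays open. Free microglial RNA was not weighed as a source. In oligodendrocyte-like nuclei the disease-associated list summed to 5645 CPM in TRAP and 2412 CPM in iPKR, and the homeostatic list to 6879 and 1646. A lower disease-associated programme in iPKR microglia may be a trait that goes with the kinase, a hypothesis found on the same data. It stays untested, because the library, its mice and its sort differ along with the kinase.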
